A study of Homo sapiens with 8 samples.

How the data were processed

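Total RNA from HTR-8/SVneo cells (labelled HTR8), an immortalised line of human trophoblast, the epithelial cell type of the placenta, was measured by RNA-seq. Per the labels' protocols, the cells were kept in medium with 10% fetal bovine serum and 1% penicillin and streptomycin. A stable CLOCK knockdown line was made with a lentivirus packaged in 293T cells, an embryonic kidney line, followed by puromycin selection. Those protocols say that green fluorescence was used to judge transfection and that the selection kept cells without it, so which cells make up the line is not clear. RNA was enriched with oligo-dT beads, fragmented and primed with random hexamers. The 8 libraries fall into 4 labelled control and 4 labelled CLOCK knockdown. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical. The knockdown came from a stably infected line, and what the control cells received is not given in the sources used here. Other differences between that line and the controls therefore cannot be separated from the knockdown.

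Base calling with CASAVA and the genome builds GRCh38 and hg38 are named in the submitters' processing notes. The aligner, the counting program and its strand setting are not given in the sources used here. The authors deposited raw counts per Ensembl gene for each library, as the whole numbers in the file show. Each count file listed 58735 genes, all of which matched GENCODE 29. The authors also deposited FPKM values for each library. For every gene with more than 50 counts, the FPKM equalled the count divided by the length of the exon union in GENCODE 29 and by a library size, within 0.1%. Those library sizes were proportional to DESeq2's size factors and not to the total counts, so the deposited FPKM already carried a scaling between libraries. Counts were the main measurement, and FPKM served as an alternative.

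Total counts were 14829328, 14905714, 15726568 and 18415820 in controls 1 to 4 and 16614608, 17861275, 17512309 and 16653356 in knockdown libraries 1 to 4. At this depth 0 counts in the 4 libraries of a group allow up to 3 counts, or 0.0470 CPM in the controls and 0.0438 CPM in the knockdown libraries, for counting error only. These limits use library size without TMM scaling, so their order between the groups has no meaning. Pearson correlations of log2 CPM were 0.986 to 0.994 within groups and 0.953 to 0.968 between groups. Within a group, the chi-square of counts per degree of freedom was 1.82 to 19.3 for every pair of libraries, so no pair agreed within sampling noise and all 8 libraries were counted.

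Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM scaling, filterByExpr and the group as the term. Adjusted p is the Benjamini-Hochberg value over the 14772 genes kept, with a threshold of 0.05, and a second count required an absolute log2 fold change of at least 1. Apart from the limits for 0 counts, CPM are scaled by TMM. Errors of CPM are SD over n = 4, and the SE of a log2 fold change comes from the model. The SE of a list median comes instead from the spread over its members, taken as independent. It is too small where members move together and does not measure the spread between libraries. CLOCK was also compared by an exact two-sided permutation test. Of 33 gene lists fixed from general knowledge, 32 had at least 5 members tested. These were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took CLOCK, every core clock gene tested, and the 8 higher and 8 lower protein-coding genes with the largest fold change. Those genes needed adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between groups. From each list it took up to 2 higher and 2 lower members with the smallest p, or the members with the highest CPM where fewer than 2 passed. It took at most 2 members by p, in either direction, from the immune, endothelial, stromal, kidney, ribosomal protein, mitochondrially encoded and histone lists. ROBO4, INA, LHX1 and SALL4 were named outside the rule.

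The alternatives were DESeq2 1.42.0, RLE, upper-quartile and library-size-only scaling, no filter, a filter of at least 10 CPM in 4 libraries, limma-voom and a replicate block. Others were limma on log2(FPKM + 1) and log2(FPKM + 0.1), removal of each library's trend on gene length and GC content (loess, span 0.3), and leaving out each library. Fold changes on the FPKM scale include the pseudocount and understate low genes. List member counts without control 4, knockdown 1 or knockdown 2, the trend removal for list tests, and 4 further gene groups were added after the data were seen.

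The test was tried on simulated counts with the genes and library sizes of this comparison, with 14608 genes tested. It recovered 36% of 50 genes changed by 1.25-fold, 64% of 50 changed by 1.5-fold, 88% of 50 changed by 2-fold and 94% of 50 changed by 3-fold, with 8 false calls and none in the wrong direction. The shifted list was called, and 0 of 30 unshifted lists were called. Each gene was simulated independently, far fewer genes were changed than in the data, and the changed genes were drawn above a minimum mean count. The trial therefore does not measure false calls for lists whose members move together, nor recovery of genes with low counts.

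Of 318 protein-coding genes whose exon bases all lie within exons of other genes, 232 had 0 counts in all 8 libraries, so counts of overlapping genes are uncertain. Because the strand setting is not known, reads of a gene and its antisense partner may be mixed. More than 20% of exon bases are shared with another gene for CSNK1E, FBXL3, NGFR, PLAU, F11R, ACTA2, SUV39H1, SUN2, NCAPG, TP53BP1, HLA-A, HOXA10 and, among genes not tested, HLA-G. Histone, ribosomal protein, PSG and HLA genes have near-identical relatives or pseudogenes, and their counts are likewise uncertain. Figures were drawn with matplotlib 3.10.9.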

Results

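RNA-seq counts were compared between 4 control libraries and 4 libraries of HTR-8/SVneo trophoblast cells with a stable knockdown of CLOCK, a transcription factor that drives the circadian clock by binding E-box sequences with ARNTL. The series addresses whether loss of CLOCK is linked to trophoblast differentiation and chromatin. Total counts per library ranged from 14829328 to 18415820. On the leading principal component, which held 66.3% of the variance, the controls lay between −40.3 and −37.4 and the knockdown libraries between 33.4 and 47.5. Control 4 lay apart from the other controls on the second component (10.8% of the variance), where knockdown 1 lay at 27.3 and the other knockdown libraries between −13.4 and −6.34. Knockdown 2 lay apart from the other knockdown libraries on the third (7.16%).

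CLOCK (ENSG00000134852, chromosome 4, 55427903 to 55547138, GRCh38) was lower in all 4 knockdown libraries. Its level was 29.142, 27.280, 32.359 and 30.862 CPM in controls 1 to 4 and 17.598, 11.881, 18.004 and 19.293 CPM in knockdown libraries 1 to 4. The mean was 29.9 ± 2.19 CPM in controls and 16.7 ± 3.29 CPM in knockdown libraries (SD, n = 4), which is 55.8% of control. An exact two-sided permutation test over 70 assignments gave p = 0.0286, the smallest it can give. In edgeR the log2 fold change was −0.84 (SE 0.12, adjusted p = 6.99e-05). With the trend of each library on gene length and GC content removed it was −0.47, with adjusted p = 4.31e-04.

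**Figure D1:**
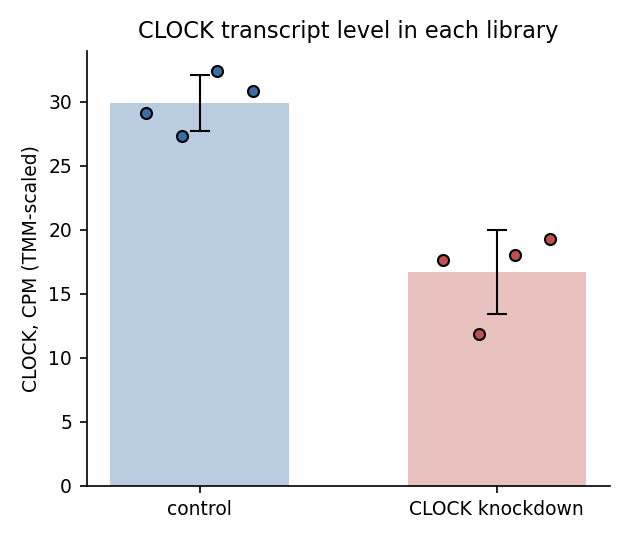
CLOCK level in CPM (TMM-scaled) in each library, with bars at the group mean and error bars of 1 SD over 4 libraries. The control libraries lie between 27.3 and 32.4 CPM and the knockdown libraries between 11.9 and 19.3 CPM.

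The comparison of all genes asked which transcripts differed between the groups (CPM as mean ± SD, n = 4 per group). HSPA5, which encodes the main chaperone of the endoplasmic reticulum (chromosome 9, 125234853 to 125241330), rose from 537 ± 5.37 to 5925 ± 97.1 CPM (log2 fold change 3.46, SE 0.04). The histone genes HIST2H2BE, HIST1H1C and HIST1H3H rose by log2 fold changes of 3.51, 2.73 and 2.48. With HSPA5 and these histone genes, NGFR, a neurotrophin receptor, RAB3A, a GTPase of secretory vesicles, AOC3, an amine oxidase, and AC010616.1 made up the 8 named for the largest rises, with log2 fold changes of 2.63, 2.13, 2.12 and 2.60. Among the lower genes, the transcription factor SOX9 went from 38.4 ± 2.57 to 4.75 ± 1.33 CPM and the integrin subunit ITGA2 from 60.1 ± 3.48 to 8.03 ± 2.07 CPM. MAT2A, which makes the methyl donor S-adenosylmethionine, went from 142 ± 4.17 to 19.6 ± 0.535 CPM (log2 fold change −2.86, SE 0.06). LCMT2, DISP1, ZNF804A, ZFHX2 and RNF207 had log2 fold changes of −3.24, −2.96, −2.95, −2.93 and −2.91.

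By edgeR's quasi-likelihood test, 9009 of 14772 genes (61.0%) changed at adjusted p under 0.05, with 4368 higher and 4641 lower. Calls in both directions within a list are therefore no sign by themselves of a change particular to that list. At least a 2-fold change was found for 1566 genes, of which 452 were higher and 1114 lower. The CPM of the groups did not overlap for 8351 genes (56.5%), where chance gives 2.86%. Scaling by library size alone gave 26.9% of called genes higher in place of 48.5%, and moved the median log2 fold change of all genes from −0.03 to −0.26. The count of 2-fold genes was 645 with a filter of at least 10 CPM in 4 libraries, and 354, 823 and 365 in the 3 tests on deposited FPKM. Of these FPKM calls 170, 313 and 177 were higher and 184, 510 and 188 lower, and with library size alone 257 were higher and 1901 lower. Across genes, which are not independent, the log2 fold change had a Spearman's rho of −0.25 with gene length, and its median was 0.25 in the second length decile and −0.33 in the longest.

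**Figure D2:**
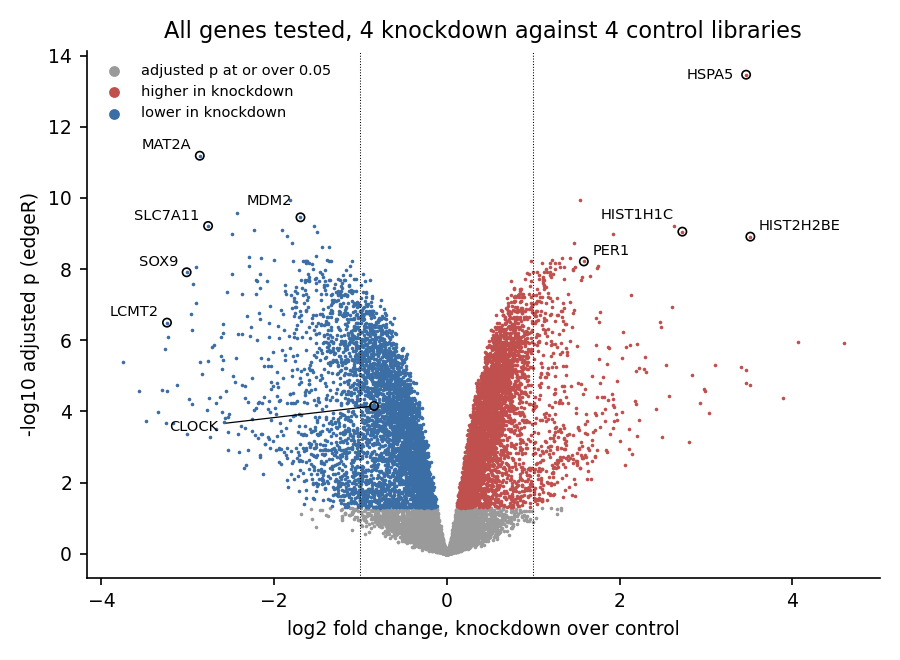
Log2 fold change (knockdown over control) against −log10 adjusted p from edgeR for the 14772 genes tested, 1 point per gene. Dotted lines mark a 2-fold change, and 1114 of the 1566 genes called beyond them are lower in the knockdown, against 184 of 354 on log2(FPKM + 1) and 1901 of 2158 with library size alone.

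Core clock genes moved in both directions. Of 21 tested, 7 rose and 9 fell, CLOCK included (7 and 10 adjusted over the list alone), and 8 rose and 6 fell with the length and GC trend removed. PER1, a repressor of CLOCK and ARNTL, rose from 68.9 ± 6.83 to 207 ± 5.69 CPM. CRY2, another repressor, rose from 7.02 ± 1.12 to 19.1 ± 1.26 CPM, and the nuclear receptor NR1D1 from 7.59 ± 0.943 to 20.9 ± 1.34 CPM. DBP, TEF and NFIL3, which bind D-box sequences, rose by log2 fold changes of 0.72, 0.48 and 0.35, and the kinase CSNK1E by 0.58. CRY1 fell from 31.9 ± 1.75 to 14.2 ± 0.377 CPM and BHLHE40, a repressor of E-box genes, from 86.7 ± 4.61 to 30.2 ± 1.22 CPM. BHLHE41, PER3, ARNTL2, RORA, ARNTL and FBXL3 fell by 2.26, 0.81, 0.75, 0.56, 0.40 and 0.25 on the log2 scale. BHLHE41 was low, going from 1.61 ± 0.374 to 0.331 ± 0.173 CPM. PER2, NR1D2, CIART, CSNK1D and TIMELESS did not pass, with log2 fold changes of −0.12, −0.01, −0.29, 0.08 and −0.12. NR1D2 had 0.14 (edgeR adjusted p = 0.0333) with the length and GC trend removed and −0.23 (0.0123) with library size alone, and CSNK1D had 0.31 (0.00205) and −0.15 (0.0172). TIMELESS passed with library size alone, with upper-quartile scaling and with the stricter filter. The calls of ARNTL, RORA, FBXL3 and NFIL3 were lost with the length and GC trend removed, and that of NFIL3 also with library size alone. That of FBXL3 was also lost without knockdown 3 (0.0524), where its log2 fold change was −0.22 against −0.25 with all libraries. Limma on log2(FPKM + 1) with no filter also lost ARNTL (adjusted p = 0.0830) and FBXL3 (0.0574). NPAS2, the paralog of CLOCK, had 0 counts in all 8 libraries. If its reads were counted, this allows up to 0.0470 CPM in controls and 0.0438 CPM in knockdown libraries, without TMM scaling. Whether its reads were counted is not known, since the counting is not described. Of 13 E-box clock targets, 5 rose and 4 fell. Neither list passed the test against other genes (camera adjusted p = 0.837 and 0.771).

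**Figure D3:**
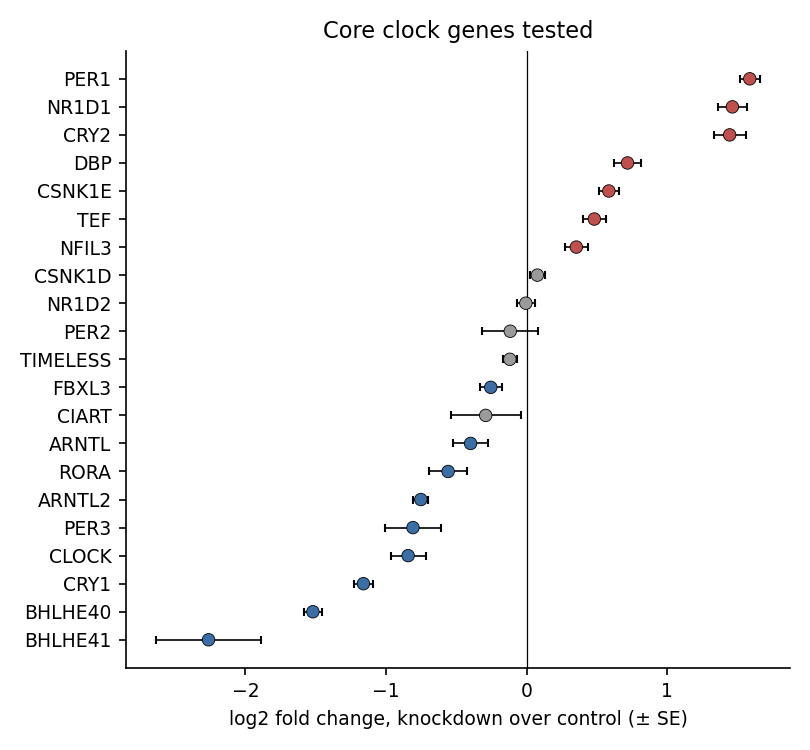
Log2 fold change (knockdown over control) of the 21 core clock genes tested, with error bars of 1 SE. Red points rose, blue points fell and grey points did not pass adjusted p of 0.05. PER1 is highest at 1.59 and BHLHE41, at 1.61 CPM in controls, lowest at −2.26.

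Trophoblast marker lists showed mixed changes. Of 30 extravillous, 41 syncytiotrophoblast and 31 cytotrophoblast genes listed, 22, 15 and 17 were tested, and the others had too few counts. Of 22 extravillous trophoblast genes, 8 rose and 3 fell, and 13 rose and 4 fell without knockdown 2. With the length and GC trend removed 13 rose and 3 fell, and the list passed (camera adjusted p = 0.0473). Over 14 alternatives with the preset correlation its adjusted p ran from 0.0473 to 0.394, and adjusted p = 0.836 with an estimated correlation. The urokinase receptor PLAUR rose from 59.3 ± 5.80 to 122 ± 12.6 CPM and FSTL3 from 42.8 ± 1.67 to 73.5 ± 8.63 CPM. PLAU and DIO2, both low, fell by 1.33 and 1.98 on the log2 scale. PLAU went from 3.19 ± 0.580 to 1.26 ± 0.239 CPM and DIO2 from 1.82 ± 0.374 to 0.457 ± 0.158 CPM. Of 15 syncytiotrophoblast and fusion genes, 3 rose and 3 fell. The stress cytokine GDF15 (log2 fold change 1.27) and the growth factor PGF (0.72) rose. PSG1 and PSG9, of a family of pregnancy-specific glycoproteins with similar sequences, both fell by 1.21. Both were low, with PSG1 going from 4.26 ± 0.0957 to 1.83 ± 0.449 CPM and PSG9 from 1.65 ± 0.574 to 0.715 ± 0.235 CPM. Of 17 cytotrophoblast and trophoblast stem genes, 5 rose and 5 fell, with GATA2 at 0.63, LRP5 at 0.41, EGFR at −0.84 and KRT18 at −0.38. Camera adjusted p for these lists was 0.316, 0.699 and 0.837. The medians of all 3 lists were above 0 with TMM and below 0 with library size alone, where 7, 3 and 3 members rose and 8, 7 and 7 fell. HLA-G, ERVW-1 and ELF5 had 0 counts in all 8 libraries, and HLA-G shares 25.8% of its exon bases with other genes. CDH1 had 15 counts in the controls and 2 in the knockdown libraries, TP63 13 and 1, CGA 5 and 1, and GCM1 0 and 1, too few to test.

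Of 17 epithelial junction genes, 2 rose and 9 fell, with the tight junction gene TJP1 down from 39.4 ± 1.97 to 15.2 ± 2.35 CPM and F11R up by 0.37 on the log2 scale. Without knockdown 2, and likewise without knockdown 1, 4 rose. The F11R call was lost with library size alone (edgeR adjusted p = 0.0503). KRT7 rose by 0.43 on the log2 scale, a call lost with library size alone and without control 1 (0.0587), control 3 (0.0524) or knockdown 4 (0.0686). Its log2 fold change was 0.20 with library size alone and 0.42, 0.44 and 0.37 without these libraries. The KRT7 call was also lost by limma on log2(FPKM + 1) with no filter (adjusted p = 0.0814, log2 fold change 0.25). Of 20 mesenchymal and EMT genes, 12 rose and 5 fell. TAGLN rose from 31.8 ± 1.60 to 94.1 ± 10.2 CPM and SPARC from 886 ± 6.87 to 1312 ± 14.3 CPM, while ACTA2 and CDH2 fell by 0.42 and 0.37. Camera adjusted p was 0.239 and 0.0544, and the second list passed without control 1 (0.0480), without control 4 (0.0425) and in 3 other settings, with a range over 14 alternatives with the preset correlation of 0.0101 to 0.138. The second list had adjusted p = 0.390 with an estimated correlation. Of 37 extracellular matrix genes, 7 rose and 17 fell (camera adjusted p = 0.342), and 11 rose and 13 fell with the length and GC trend removed. CTGF, a matricellular YAP target, rose from 53.1 ± 1.94 to 127 ± 5.42 CPM and CYR61, another, by 0.93 on the log2 scale, and the collagen genes COL3A1 and COL5A1 fell by 0.97 and 0.78. Of 19 TGF-beta and YAP targets, 7 rose and 8 fell, the latter including SMURF2 and AJUBA. Of 14 angiogenic factors, 4 rose and 6 fell, with TIE1 at 0.88, SERPINE1 at 0.50, VEGFA at −0.996 and FGF2 at −0.62. Of 20 Wnt and Notch targets, 4 rose and 4 fell, with HES4 at 0.75, NKD2 at 0.47, DKK1 at −0.97 and TCF7 at −1.10.

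Chromatin genes also moved both ways. Of 32 heterochromatin and nuclear lamina genes, 10 rose and 14 fell, and 12 rose and 10 fell with the length and GC trend removed. SMCHD1, a silencing factor of the SMC family, fell from 79.5 ± 2.69 to 25.4 ± 3.90 CPM and FAM208A, a subunit of the HUSH silencing complex, from 82.3 ± 2.29 to 31.5 ± 1.61 CPM, while the histone methyltransferase SUV39H1 rose from 49.0 ± 4.46 to 91.3 ± 5.72 CPM and SUN2 by 0.54 on the log2 scale. Of 17 DNA methylation genes, 4 rose and 11 fell, with ZBTB38 and HELLS down by 1.24 and 0.93 and UHRF2 and MECP2 up by 0.51 and 0.32, the latter not called with library size alone. Of 34 Polycomb genes, 9 rose and 17 fell, or 13 and 11 with that trend removed, with PCGF1 at 1.23, RNF2 at 0.47, MTF2 at −0.75 and RING1 at −0.59. Of 55 histone acetylation and remodelling genes, 18 rose and 17 fell, with KAT8 at 0.86, BRD2 at 0.82, KAT2B at −0.99 and HDAC1 at −0.46. None of the 4 lists passed the test against other genes (camera adjusted p = 0.502, 0.0686, 0.581 and 0.858). With the trend removed, 27 members of the acetylation and remodelling list rose and 11 fell, and it passed (adjusted p = 0.00324, with a range over 14 alternatives with the preset correlation of 0.00324 to 0.947). It had adjusted p = 0.921 with an estimated correlation. With library size alone, 8 of its members rose and 32 fell.

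The replication-dependent histone list was the list with the highest median. Of 28 genes listed, 14 had enough counts to be tested. Of these 14, 13 rose and none fell, with a median log2 fold change of 1.91 (camera adjusted p = 3.04e-06). The filter lets a low gene enter through 1 group alone, so the count and median may favour genes that changed. With an estimated correlation the adjusted p was 0.223. The RNA was enriched with oligo-dT beads, so these counts do not show whether total histone RNA rose. HIST2H2BE rose from 2.22 ± 0.468 to 25.4 ± 1.31 CPM and HIST1H1C from 11.9 ± 0.922 to 79.2 ± 9.15 CPM. RN7SL2, a structural RNA without a poly(A) tail, was at 109 ± 11.3 CPM in controls and 118 ± 9.74 CPM in knockdown libraries (edgeR adjusted p = 0.207). Of 47 DNA replication and S phase genes, 16 rose and 19 fell (camera adjusted p = 0.581), with the licensing factors CDT1 and ORC1 up by 0.75 and 0.61 and E2F8 and POLA1 down by 1.22 and 0.96. The S phase list passed with the length and GC trend removed (0.0330), with a range over 14 alternatives with the preset correlation of 0.0330 to 0.806, and adjusted p = 0.869 with an estimated correlation. Of 61 mitosis genes, 34 rose and 18 fell (camera adjusted p = 0.0544). The spindle factor TPX2 rose from 406 ± 8.11 to 695 ± 15.5 CPM and CDK1 from 213 ± 7.96 to 368 ± 17.9 CPM, while CENPE and NCAPG fell by 1.51 and 0.90. The mitosis list passed without control 1 (0.0482), control 4 (0.0465), knockdown 2 (0.04575) or knockdown 4 (0.0492) and with library size alone (0.0403), where 25 members rose and 25 fell. Its range over 14 alternatives with the preset correlation was 0.0403 to 0.174, and adjusted p = 0.390 with an estimated correlation.

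Of 57 DNA damage repair genes, 10 rose and 28 fell (camera adjusted p = 0.0463; adjusted p = 0.677 with an estimated correlation). TP53BP1, a double-strand break factor, fell from 108 ± 6.57 to 35.7 ± 4.27 CPM and FANCI from 165 ± 3.96 to 86.5 ± 4.69 CPM, while XRCC6 and PARP2 rose by 0.61 and 0.62 on the log2 scale. With the length and GC trend removed 20 rose and 26 fell. The list did not pass there (adjusted p = 0.997), nor did it with the replicate block (0.0614) or without knockdown 2 (0.06235), knockdown 3 (0.0533) or knockdown 4 (0.0713). The list's mean relative to other genes was −0.21, and it was 0.0065 with the trend removed, −0.21 with the block and −0.18, −0.21 and −0.20 without these libraries. Of 28 p53 targets, 7 rose and 13 fell (camera adjusted p = 0.460). MDM2, the ligase that degrades p53, fell from 194 ± 4.77 to 59.9 ± 1.83 CPM and TP53INP1 from 20.3 ± 1.45 to 6.08 ± 0.629 CPM, while GDF15 and TRIAP1 rose.

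Of 33 interferon response genes, 6 rose and 17 fell (camera adjusted p = 0.0441; adjusted p = 0.559 with an estimated correlation). PARP9 and PARP14 fell by 1.26 and 1.18, and UBE2L6 and USP18 rose by 0.36 and 0.55. With library size alone the list had adjusted p = 0.0906 and with the replicate block 0.0614. Its range over 14 alternatives with the preset correlation was 0.00358 to 0.0906. The list's mean relative to other genes was −0.46 in the main test, with library size alone and with the block. The UBE2L6 call was lost with library size alone. IFNB1 had 0 counts in all 8 libraries. Of 15 genes of MHC class I presentation, 4 rose and 7 fell (camera adjusted p = 0.762), with HLA-E at 0.65, HLA-A at 0.36, ERAP1 at −0.65 and ERAP2 at −0.57. Of 18 inflammatory and secretory genes, 3 rose and 7 fell (camera adjusted p = 0.581), with IL11 at 1.07, IL1B at 0.61, NFKBIA at −1.30 and BIRC3 at −1.38.

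Of 36 unfolded protein and amino acid stress genes, 22 rose and 7 fell (camera adjusted p = 6.41e-04; adjusted p = 0.341 with an estimated correlation), and 23 rose and 4 fell without knockdown 1. Besides HSPA5, HERPUD1, a factor of endoplasmic reticulum protein degradation, rose from 24.0 ± 1.93 to 67.0 ± 2.44 CPM. SLC7A11, the cystine transporter, fell from 106 ± 4.66 to 15.7 ± 2.28 CPM, and EDEM1, which also serves protein degradation, from 90.7 ± 1.56 to 43.9 ± 3.01 CPM. Of 28 cholesterol synthesis genes, 17 rose and 4 fell (camera adjusted p = 0.00459; adjusted p = 0.390 with an estimated correlation), and 13 rose and 10 fell with library size alone. MSMO1 rose from 60.5 ± 4.64 to 229 ± 13.5 CPM and INSIG1 from 74.4 ± 4.14 to 206 ± 5.54 CPM, while TM7SF2 and the transcription factor SREBF1 fell by 1.26 and 1.04. Of 34 hypoxia and glycolysis genes, 20 rose and 11 fell (camera adjusted p = 0.145), with GAPDH at 0.72, SLC2A3 at 0.62, PDK1 at −1.18 and PFKFB4 at −1.19.

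Of 74 ribosomal protein genes, 72 rose and none fell, with a median log2 fold change of 0.68 (camera adjusted p = 8.44e-17; adjusted p = 0.646 with an estimated correlation). The median was 0.45 with library size alone. RPL12 rose from 919 ± 20.5 to 1734 ± 161 CPM and RPL4 from 1714 ± 13.3 to 2822 ± 175 CPM. Of 313 processed pseudogenes, a class with many copies of ribosomal protein genes, 87 rose and 23 fell. Of 60 nuclear genes of mitochondrial oxidative phosphorylation, 54 rose and none fell, with a median of 0.48 (camera adjusted p = 5.18e-11; adjusted p = 0.657 with an estimated correlation). With library size alone the median was 0.24, and 39 rose and 1 fell. CYC1 rose from 183 ± 17.3 to 317 ± 23.0 CPM and SDHA from 397 ± 14.2 to 558 ± 25.3 CPM. Of 13 mitochondrially encoded protein-coding genes, none rose and 7 fell (camera adjusted p = 0.111). Mitochondrial ribosomal RNA, outside this list, held 0.318% to 0.367% of counts in controls and 0.426% to 0.465% in knockdown libraries. MT-CYB fell from 661 ± 22.5 to 229 ± 8.50 CPM and MT-CO3 from 980 ± 35.5 to 679 ± 49.9 CPM. This list passed with the length and GC trend removed (0.00358), with a range over 14 alternatives with the preset correlation of 0.00358 to 0.205, and adjusted p = 0.677 with an estimated correlation.

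**Figure D4:**
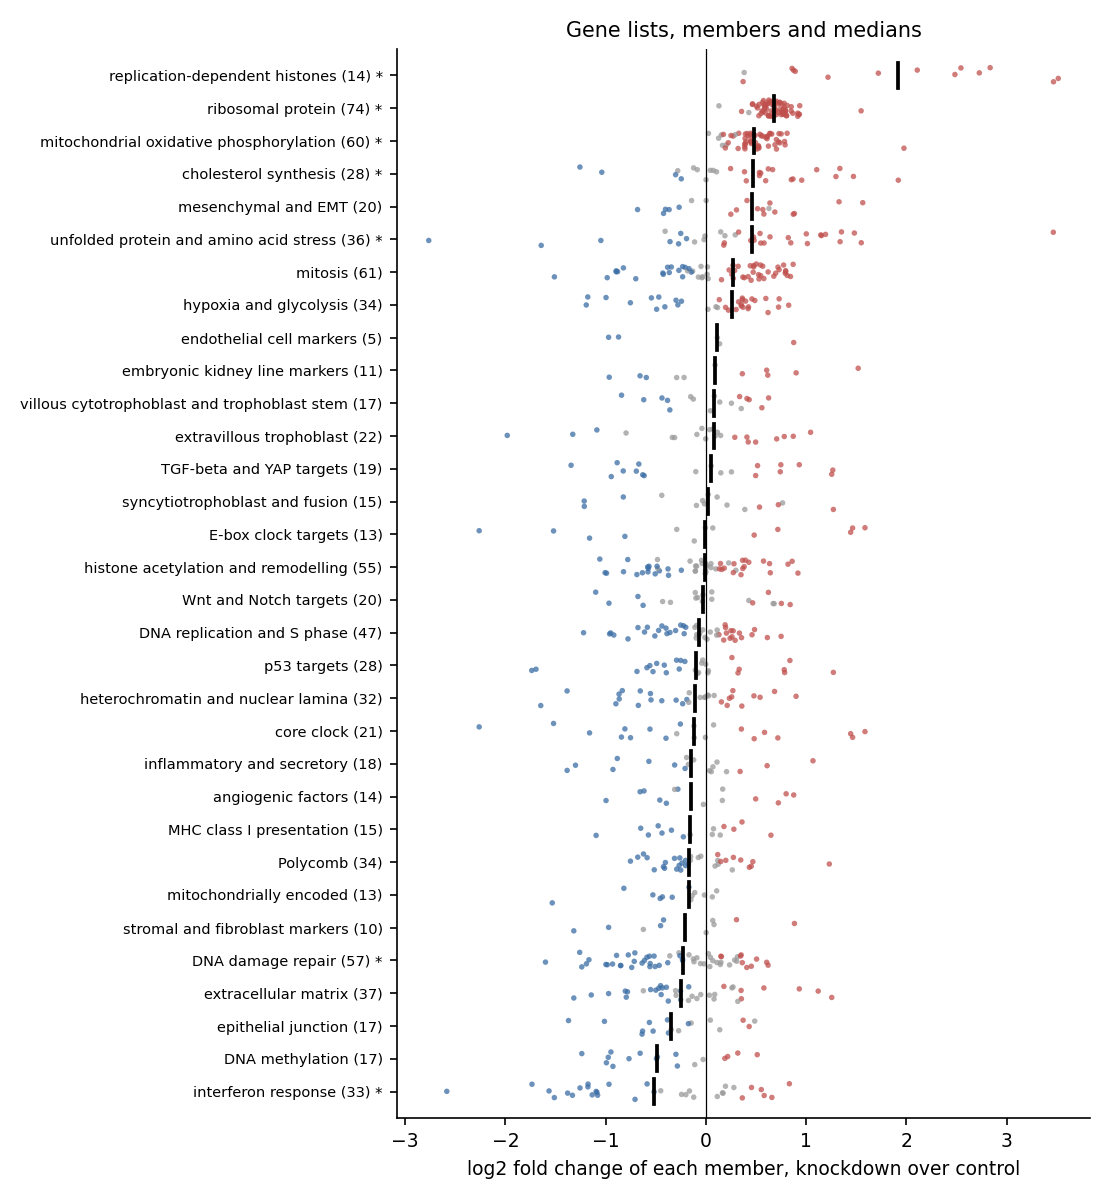
Log2 fold change (knockdown over control) of each tested member of the 32 gene lists with at least 5 members, with the number tested in brackets. Red points rose, blue points fell and grey points did not pass adjusted p of 0.05. Black bars are list medians, and stars mark the 7 lists past camera adjusted p of 0.05. The ribosomal protein members rose in 72 of 74 cases.

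Of the markers of other cell types, 1 of 19 immune, 5 of 16 endothelial, 10 of 18 stromal and 11 of 17 kidney markers were tested. Those called moved in both directions. Of 5 endothelial markers tested, 1 rose (TIE1) and 2 fell (MMRN2 by 0.97 and ROBO4 by 0.87). Of 10 stromal and fibroblast markers, 2 rose, including TWIST2 by a log2 fold change of 0.88, and 4 fell, including COL3A1. Of 11 embryonic kidney line markers, 5 rose and 3 fell, with GAL going from 2.45 ± 0.587 to 7.01 ± 1.10 CPM and HOXA10 from 15.2 ± 1.38 to 28.4 ± 1.68 CPM. The 3 lower members were INA (log2 fold change −0.66), LHX1 (−0.59) and SALL4 (−0.96). These 3 genes and ROBO4 were named after their values were seen. The only immune marker tested, CD14, was at 1.15 ± 0.119 CPM in controls and 0.753 ± 0.271 CPM in knockdown libraries (adjusted p = 0.0926). It passed without knockdown 2 (0.0350), with library size alone (0.0238) and with the length and GC trend removed (0.0227). Camera adjusted p was 0.878, 0.581 and 0.579 for the endothelial, stromal and kidney lists, 0.837 for the TGF-beta and YAP and the angiogenic lists, and 0.878 for the Wnt and Notch list. None of the 7 camera calls held with an estimated correlation, where the smallest adjusted p was 0.223. Adjusted over the list alone, the numbers higher and lower were 3 and 2 for the syncytiotrophoblast list, 4 and 9 for epithelial junctions, 7 and 18 for extracellular matrix and 10 and 17 for Polycomb. They were 8 and 18 for interferon response, 24 and 7 for unfolded protein stress, 55 and 0 for oxidative phosphorylation and 0 and 6 for mitochondrially encoded genes. For the other lists, the core clock aside, the counts adjusted over the list alone equalled those over all genes. The medians of the TGF-beta and YAP, kidney and endothelial lists also went below 0 with library size alone. In 6 lists the median, the mean and the direction of the test differed in sign. These were the E-box, extravillous, acetylation and remodelling, Wnt and Notch, TGF-beta and YAP, and endothelial lists.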

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

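None of the tests in this part was chosen after a result was seen. A library stood apart from the other 3 of its group, by a gap to the nearest of them that took most of the group's range (beyond Dixon's 95% critical value), in 29 of 296 groups of values, where chance gives about 1 in 20, or 15 groups. Knockdown 2 accounted for 12 of them and control 4 for 9. Members of the same library are not independent, so the excess has no test.

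Control 4 was lower than the other controls for CSNK1E (52.4 CPM, others 62.0 to 63.6, gap 0.853 of the range), PLAUR (50.7, others 61.6 to 63.3, gap 0.863) and COL5A1 (163, others 187 to 192, gap 0.845). It was also lower for CDT1 (217, others 253 to 255, gap 0.951), TP53INP1 (18.2, others 20.8 to 21.3, gap 0.836), HLA-E (428, others 471 to 480, gap 0.835) and SREBF1 (177, others 228 to 235, gap 0.882). Its share of counts in processed pseudogenes was 0.588% against 0.487% to 0.492% (gap 0.951), and in processed transcripts 0.223% against 0.204% to 0.206% (gap 0.895).

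Knockdown 2 was higher than the other knockdown libraries for CSNK1D (154 CPM, others 145 to 146, gap 0.944), FSTL3 (86.3, others 68.2 to 70.2, gap 0.893), F11R (85.0, others 73.3 to 74.2, gap 0.923) and PCGF1 (30.5, others 21.2 to 22.5, gap 0.864). The same held for CDT1 (461, others 389 to 401, gap 0.8294), HERPUD1 (70.6, others 65.3 to 66.0, gap 0.863) and RPL4 (3083, others 2716 to 2753, gap 0.901). It was lower for BRD2 (256, others 301 to 307, gap 0.887), E2F8 (6.78, others 7.65 to 7.81, gap 0.846) and PARP14 (22.3, others at least 28.4, gap 0.905). Its 10 most counted genes held 8.34% of counts against 7.84% to 7.89% (gap 0.900). On the third principal component it lay at 29.2 against −14.0 to −8.32 (gap 0.868).

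In knockdown 1, HELLS was lower (34.9 CPM, others 39.6 to 39.9, gap 0.940) and HDAC1 higher (207, others 200 to 201, gap 0.837). In knockdown 3, ZFHX2 was higher (1.40, others 0.978 to 1.03, gap 0.880). In control 2, MAT2A (136, others 144 to 145, gap 0.882) and SLC7A11 (99.5, others 108.5 to 109.2, gap 0.935) were lower and RPL12 higher (950, others 905 to 911, gap 0.856). In control 3, NCAPG was lower (137, others 138.5 to 138.7, gap 0.901). In control 1, GAL was higher (3.33, others 2.12 to 2.23, gap 0.905).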

How the results depend on the processing

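The trend removal for list tests and the list counts without control 4, knockdown 1 or knockdown 2 were chosen after the data were seen. CLOCK was lower and past the threshold under all 21 alternatives, with log2 fold changes from −1.07 (library size only) to −0.47 (length and GC trend removed). The count of changed genes stayed within 1.5 times of 9009, from 7045 to 9486, and was 8417 to 9216 with 1 library left out. A similar count did not mean the same genes. Of the 9009, 7197 were also called with library size alone and 7867 with the length and GC trend removed, whatever their direction. The count of 2-fold genes was 1525 to 1698 with 1 library left out. It was 645 with at least 10 CPM in 4 libraries, 354 on log2(FPKM + 1), 823 on log2(FPKM + 0.1) and 365 on log2(FPKM + 1) with no filter. The stricter filter tested fewer genes (9727), and the larger pseudocount shrinks the fold of low genes, as the rise from 354 to 823 shows. Depth limits the genes with low counts, and 2201 genes passed 2-fold with no filter. DESeq2 called 8895 genes and gave 1864 of at least 2-fold.

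The count of lists past the threshold was 7, 0 with an estimated correlation, 24 with fry, 11 with the length and GC trend removed, and 6 to 9 with 1 library left out. Fry does not compare a list with other genes. The relative mean of the DNA damage repair list was −0.21 and reversed to 0.0065 with the length and GC trend removed. Of 134 named genes besides CLOCK, 128 passed. Of these, 120 kept their direction and call in every setting that tested them, while 8 lost the call in at least 1 setting. Most were named for a small p or a large fold change in these libraries, so the 120 do not show how other genes hold. The 8 included ARNTL, RORA, NFIL3 and FBXL3, core clock genes named whatever their p. NR1D2, not called with TMM, turned to 0.14 with the length and GC trend removed and to 0.14 with the replicate block as well, and CSNK1D, not called either, turned to −0.15 with library size only. For the other changes the cause was not tested.

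Nothing in the labels pairs the libraries by number. Deviations from the group means correlated at r = 0.30, 0.05, −0.06 and 0.22 for the same numbers. Controls 1, 2 and 4 correlated best with the knockdown library of their own number, while control 3 correlated best with knockdown 1 (0.17) and knockdown 3 best with control 4 (0.16). With the replicate block, 9194 genes changed, 1603 at least 2-fold, the CLOCK log2 fold change was −0.85, and 5 lists passed. With the block and the trend removal together the counts were 9381 and 1471.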

Other observations

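Chosen after results were seen were the tests of S phase, clock phase, NPAS2 and short-lived transcripts, the need for 3 structural RNAs at 5 CPM, and all gene groups added here. Of 21 translation factors and related genes whose transcripts start with a 5' terminal oligopyrimidine tract, 20 rose and none fell, with a median log2 fold change of 0.49 (camera adjusted p = 1.63e-07, adjusted p = 0.0794 with an estimated correlation). Of 13 host genes of small nucleolar RNAs, 10 rose and 1 fell, with a median of 0.76 (camera adjusted p = 4.63e-04, adjusted p = 0.211 with an estimated correlation). EEF1A1, the most counted gene, held 2.05% to 2.22% of counts in controls and 3.11% to 3.34% in knockdown libraries. Of 1091 antisense genes, 97 rose and 234 fell, though reads of antisense partners may be mixed where strand is not known.

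Whether chance could place the libraries this way was tested over the 35 splits of the 8 libraries into 4 and 4. Only 1 split, the real one, gave as many as 9009 changed genes, 1566 genes of at least 2-fold or 7 lists. The highest values of the other splits were 0, 0 and 6. For both gene counts 1 of 35, the smallest share possible, argues against a chance split if the libraries are independent, which the labels do not say. Every other split mixes the groups, which widens the spread within each side. Chance differences between the lines were not tested. The list count gives no such ground, since 4 other splits gave 6 lists with 0 changed genes, and the real count was 5 with the replicate block, 6 without knockdown 3 and 0 with an estimated correlation.

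Ribosomal protein and oxidative phosphorylation genes rose together. With the length and GC trend of each library removed, the median log2 fold change was 0.6226 (SE 0.029) for the ribosomal protein list. It was 0.4188 (SE 0.045) for the oxidative phosphorylation list, so the trend as measured was not the whole source of either. Length here was the union of a gene's annotated exons, which can be longer than the transcript expressed. An effect of transcript length therefore stays open. Members of these lists moved together (estimated correlation 0.70 and 0.57 before the trend was removed), so these SEs are too small. Over 3 other scalings the lowest median was 0.2448, that of oxidative phosphorylation with library size alone (0.48 with TMM), so the scaling factors set part of its size but were not the whole source. Reads of processed pseudogenes and differences between the lines other than CLOCK stay open, and no biological explanation was tested.

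Counts of replication-dependent histone transcripts rose for 13 of the 14 tested, of 28 listed. Oligo-dT enrichment leaves open whether their total RNA did. A larger share of cells in S phase would raise the S phase genes, but their median log2 fold change was −0.0661 (SE 0.080), against 1.91 (SE 0.37) for the histones, with 16 of 47 higher and 19 lower. Carry-over of RNA without a poly(A) tail cannot be told apart from a true rise. The median of the 5 small structural RNAs tested was −0.0805 (SE 0.30), below the bound of 0.5 that was set beforehand to argue against it. That bound was wrong for these genes, because only RN7SL2 reached 5 CPM (109 ± 11.3 CPM in controls, 118 ± 9.74 CPM in knockdown libraries), and genes near the floor exclude nothing.

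E-box clock genes moved in both directions while CLOCK fell. So did genes at large, with 61.0% of those tested called and 48.5% of these higher. Of 7 genes whose peaks lie close together, PER1, NR1D1, DBP and TEF rose, 1 (PER3) fell, and NR1D2 and CIART did not pass. The bound written to argue against a shift of clock phase, at least 1 gene called against the others, was met by PER3. That bound was not applied, since 1 gene seen before the test was written decides nothing. A shift of clock phase at harvest therefore cannot be told apart. All 16 called core clock genes lay farther from 0 (at least 0.25) than they moved under other scaling factors (at most 0.23), so 0 changed sign. Scaling moves all genes nearly alike, so this was no separate test, but such a shift alone cannot give both directions. The counts did depend on it, with 6 higher and 12 lower with library size alone against 7 and 9 with TMM. NPAS2 standing in for CLOCK would need its transcript, which had 0 counts in the 4 knockdown libraries, unless its reads were lost in counting, which was not tested beyond the 6.3% of its exon bases shared with other genes.

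Zinc finger genes fell more often than they rose, with 74 of 424 higher and 207 lower (camera adjusted p = 1.99e-04, adjusted p = 0.151 with an estimated correlation). The hypothesis that the length and GC trend was the whole source is not borne out for length taken as the exon union. The median went from −0.28 to −0.1983 (SE 0.039) with that trend removed. An effect of the length of the transcript expressed stays open here too. The hypothesis that short-lived transcripts were lost as a class could not be decided, with a median of −0.1079 (SE 0.13) over 65 listed genes, of which 20 rose and 28 fell.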
